A study of Homo sapiens with 4 samples.

How the data were processed

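The series holds 4 Illumina BeadChip expression arrays of total RNA from macrophages derived from THP-1, an established human acute monocytic leukemia line that grows as monocyte-like cells. Each of 4 groups, M0, M1, M2a and M2c, has 1 array. Per the labels' protocols, unpolarised M0 macrophages were driven to M1 by interferon-gamma with lipopolysaccharide (LPS), to M2a by interleukin-4 and to M2c by interleukin-10. Doses, exposure times and the agent that made macrophages of the THP-1 cells are not given in the sources used here. RNA was extracted with Trizol, checked with a NanoDrop and turned into biotin-labelled cRNA with a TargetAmp-Nano kit, per the labels' protocols.

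The authors deposited a non-normalized and a normalized table, each with an intensity and a detection p-value for 47228 probes per array, and a value table. Intensities are on a linear scale. A detection p-value is the chance that a negative-control bead reads as high as the probe. GenomeStudio is named as the software, per the submitters' processing notes, with no version. Tested on the values, the deposited normalized intensity was a quantile normalization of the non-normalized signals, since the sorted columns lay within 0.12% of the mean of the sorted raw signals. The value table differed from the normalized table in 0 cells. The detection p-values of the deposited files differed in 10 cells, and those of the non-normalized table were used. Every column was matched to a group by name, with 0 columns left over. Each intensity column followed its own detection p-values, with a rank correlation of at least 0.99 in size against at most 0.86 for those of another array.

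Starting from the non-normalized intensities, the background was corrected by the normexp method of limma 3.58.1 (neqc, in R 4.3.3), with negative-control mean and spread inferred from the detection p-values and an offset of 16, followed by quantile normalization of the 4 arrays and log2. The offset pulls differences of dim probes towards 0, so log2 differences of weak genes are understated. A probe with a detection p below 0.01 was called detected. Of the probes, 30111 carried 1 gene symbol in the platform annotation, 8 carried several and 17109 were unnamed here. Symbols were brought up to date through Entrez identifiers for 30072 probes with the RefSeq gene table of GRCh38.p14. No gene was named from a probe with several symbols. The probe with the highest mean over the 4 arrays stood for each of 20045 genes, of which 6690 had more than 1 probe and 10395 were detected on at least 1 array. Probes shared by near-identical genes (HLA-DRB genes, HLA class I genes, CCL3L1, CCL3L3, CCL4L1, NCF1, FCGR1A with FCGR1BP, metallothioneins, C4 genes) make the values of these genes uncertain. Counts and percentiles of gene lists take such genes as separate members, although their readings may not be independent.

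With 1 array per group there is no replicate, so no test was run, no p-value is given across genes, and none of the differences has a replicate check. Array, culture, RNA preparation and any batch cannot be told apart from the group. A gene was called higher or lower by a fixed rule of size: at least 2-fold (1.0 on the log2 scale) between the 2 arrays, and detected on at least 1 of them. The verbs rose and fell are used of genes past that rule. For a gene detected on only 1 of the 2 arrays the fold is given as a bound ("at least"): the normalized value on the bright array against the higher of the gene's own value on the dim array and the lowest value of any detected probe there. Such a bound holds for the main normalization only, and other treatments of the background give smaller folds. Counts of higher and lower genes use the measured values. The 6 pairs of groups were compared.

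Named genes follow a rule fixed before the data were examined. For each polarised group against M0 it takes the 8 largest rises and 8 largest falls among genes detected on both arrays. It adds the 5 brightest genes detected on only 1 array in each direction with a bound of at least 2-fold, and the 4 members of each list with the largest change. Between polarised groups it takes the 5 largest rises and 5 largest falls among genes detected on both arrays. Genes named outside the rule are said to be so. The 35 gene lists were fixed at the same time. A list's median log2 difference covers its members detected on at least 1 array, and its percentile is its rank among 10000 random lists of the same size matched on mean value in 20 bins, for lists of at least 5 detected genes. The percentile describes these arrays and does not replace replicates. List members that are not named were in part not analysed here.

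The procedure was tested on simulated data, with known changes placed on a simulated M1 array against M0, an array noise of 0.18 on the log2 scale and 50 genes per fold. Of genes changed 2.5-fold, 41 were called (82.0%), of those changed 4.0-fold 46 (92.0%) and of those changed 8.0-fold 48 (96.0%), while 0 of 50 changed 1.5-fold and 6 of 10234 unchanged genes (0.06%) passed. Estimates were pulled in, with a median of 2.64 for a true 3.0 on the log2 scale. All other genes were left unchanged, while 34.01% of tested genes changed between the measured M1 and M0 arrays. The simulation therefore did not test scaling with that much change, and 0.06% is no false-call rate for the measured arrays. For overlaps of comparisons that share the M0 array, 100 sets of unchanged arrays were simulated, with noise taken from the M2c and M0 pair, the closest of the 6. These hold no real change, so they cannot show how noise of the M0 array adds to real changes. Alternatives, all but the last planned before the data were examined, were the authors' normalized table, scaling of the arrays to a common median without quantile normalization, no background correction, an offset of 50, a detection p below 0.05, detection on both arrays, no detection filter, the mean over probes, a 3-fold rule, and normalization without the M1 array, which was added after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.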

Results

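Gene expression was measured on 4 bead arrays of THP-1 macrophages: 1 of unpolarised M0 cells, 1 of M1 cells made with interferon-gamma and LPS, 1 of M2a cells made with interleukin-4 (IL-4) and 1 of M2c cells made with interleukin-10 (IL-10). With 1 array per group the differences have no replicate check, and array and group cannot be told apart. The M0 array detected 14818 of 47228 probes (31.4%), the M1 array 12937 (27.4%), the M2a array 14280 (30.2%) and the M2c array 13673 (29.0%), with median raw signals of 110.7, 102.9, 110.4 and 110.9 intensity units. Across the 10988 probes detected on all arrays, which are not independent replicates, the log2 values of M2c and M0 correlated with r = 0.989, those of M2a and M0 with 0.96, and those of M1 and M0 with 0.853.

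The first comparison asked what interferon-gamma and LPS changed. The M1 array carried a large inflammatory program. CCR7, the chemokine receptor that guides cells to lymph nodes, was at least 449-fold higher than on the M0 array, IDO1, which degrades tryptophan, at least 444-fold, ACOD1, which makes itaconate, at least 126-fold, CXCL9, a chemokine for T cells, at least 119.6-fold and HLA-DPA1, an MHC class II chain, at least 112-fold. These bounds hold for the main normalization: the lowest log2 differences over the alternatives for values were 7.55 for CCR7, 7.26 for IDO1, 5.51 for ACOD1, 5.68 for CXCL9 and 5.44 for HLA-DPA1, which are smaller folds. Cell cycle genes and the lipid regulator PPARG were lower. In all, 1494 genes were higher and 1902 lower of 9986 tested, and 212 rose but 46 fell by at least 8-fold.

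Interferon-gamma targets moved almost as a block. Of 25 detected members of that list 24 rose, 0 fell and 1 did not pass, with a median log2 difference of 3.99 (percentile 100 among random lists), or 3.75 with undetected sides at their bound. SERPING1, the C1 inhibitor, rose by 5.95 and GBP5, a guanylate-binding protein of antimicrobial defence, by 5.73 on the log2 scale. Among type I interferon-stimulated genes 29 of 36 rose and 0 fell (median 1.71, percentile 100), led by ISG20 (5.12), RSAD2 (4.38), OASL (4.25) and IFIT2 (3.43), which act against viruses.

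LPS-type mediators rose with them. Of 19 detected cytokines and mediators 16 rose and 0 fell (median 3.49, percentile 100). IL6 was at least 74.6-fold higher by the main normalization (lowest log2 difference over the alternatives 4.94), IL23A rose by 6.57 (lowest 4.99) and IL1B by 5.63 (lowest 5.31). Of 18 inflammatory chemokines 17 rose (median 3.93, percentile 100). They included CCL4L1 (6.09, against 1.64 for its other probe), CCL3L1 (5.88), CCL3 (5.77) and CCL8 (5.74), while CCL19 was at least 32.2-fold higher. All 21 detected genes of the NF-kappaB list rose (median 2.74, percentile 100). The list holds components and feedback inhibitors of NF-kappaB and also genes that are neither, such as TNFAIP6 and CD80. TNFAIP6 was up by 5.87 and IER3 by 5.66. TRAF1 was at least 48.2-fold higher (3.36 on the log2 scale for its other probe), and the T cell costimulator CD80 at least 41.0-fold. Metallothioneins and zinc transporters, which handle metal ions, had 8 of 10 higher (median 2.92, percentile 100), led by MT2A (5.39). Probes of the CCL3L and metallothionein families can read more than 1 paralog.

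Antigen presentation genes were also higher. Of 14 MHC class II genes 12 rose (median 2.92, percentile 100), among them HLA-DRB5 (5.54), the invariant chain CD74 (3.60) and HLA-DRA (3.57, against 6.70 for its other probe). The 12 include HLA-DRB1, HLA-DRB3, HLA-DRB4, HLA-DRB5 and HLA-DRB6, whose probes can read more than 1 of these genes. Of 19 MHC class I and immunoproteasome genes 12 rose (median 1.10, percentile 100), and all 19 did with arrays scaled to a common median. The immunoproteasome subunit PSMB9 rose by 3.12, the peptide transporter TAP1 by 2.31 and PSME2 by 1.75. The largest rise among genes detected on both arrays was that of CKB, the brain-type creatine kinase, at 171-fold (7.41 on the log2 scale, lowest over the alternatives for values 6.16). Of 23 Toll-like receptor and inflammasome genes 15 rose and 3 fell (median 1.59, percentile 100), or 11 and 1 in the authors' table (median 0.90). The DNA sensor AIM2 was up by 4.78 (1.93 for its other probe) and the kinase IRAK2 by 4.53.

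The falls on the M1 array included lipid genes. PPARG, a nuclear receptor that drives lipid storage genes, fell by 4.30 on the log2 scale, or 19.7-fold (smallest fall over the alternatives for values -3.32), and its target FABP4, a fatty acid carrier, fell by 3.32. Of 20 genes of lipid uptake and of LXR or PPAR targets 10 fell and 3 rose (median -0.97, percentile 0.05). LPL, lipoprotein lipase, was at least 8.08-fold lower, whereas NR1H3, the nuclear receptor LXR-alpha, rose by 4.46. The other largest falls were of PCM1 (-4.02), GRAMD4 (-3.84), IMPA2 (-3.45), BMP8B (-3.44), the thromboxane synthase TBXAS1 (-3.39) and BRI3BP (-3.32, against a mean of -0.55 for its 3 other probes). ANTXR1 was at least 40.3-fold lower, PHACTR3 at least 24.6-fold, NT5DC2 at least 17.4-fold, the scavenger receptor COLEC12 at least 17.4-fold and the fractalkine receptor CX3CR1 at least 16.8-fold, with smaller changes for the other probes of ANTXR1 (mean -1.27 over 3), PHACTR3 (-3.13) and CX3CR1 (-1.41). Over the alternatives for values the smallest falls of these genes were -4.08, -3.32, -2.83, -3.33 and -2.98 in the same order, below the bounds of the main normalization in size.

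Proliferation genes were lower on the M1 array. Of 36 cell cycle genes 30 fell, CCND1 rose and 5 did not pass (median -1.45, percentile 0.0), with TOP2A, a DNA topoisomerase, at -3.29, STMN1 at -2.50, NUSAP1 at -2.36 and CDKN3 at -2.26. CCND1 is outside the rule for named genes and was named after its value was seen; 0 of the genes rose in the authors' table or with an offset of 50. Of 26 ribosomal protein genes 9 fell, RPS23 (-2.49), RPS3 (-1.27) and RPL5 (-1.26) the most (median -0.79, percentile 0.01), but 1 fell and the median was -0.14 with arrays scaled to a common median. Genes of long loci were lower on the M1 array as a whole: in 5 equal groups from the shortest to the longest genomic length, the median log2 difference was 0.01, -0.11, -0.24, -0.21 and -0.37.

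Among the genes past 2-fold with another detected probe, 713 of 772 (92.4%) moved the same way on the mean of the other probes, and 489 (63.3%) passed 2-fold there. The balance of rises and falls depended on the processing: 44.0% of changed genes were higher by the main method. With arrays scaled to a common median the share was 61.3% (1960 higher and 1236 lower). In the authors' table, which is also quantile normalized, it was 51.6%. It was 51.7% without background correction and 47.3% with an offset of 50. Among genes detected on both arrays it was 49.4% (1094 higher and 1121 lower). The median of the 10395 detected genes moved from -0.17 to 0.12 with common-median scaling.

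**Figure D1:**
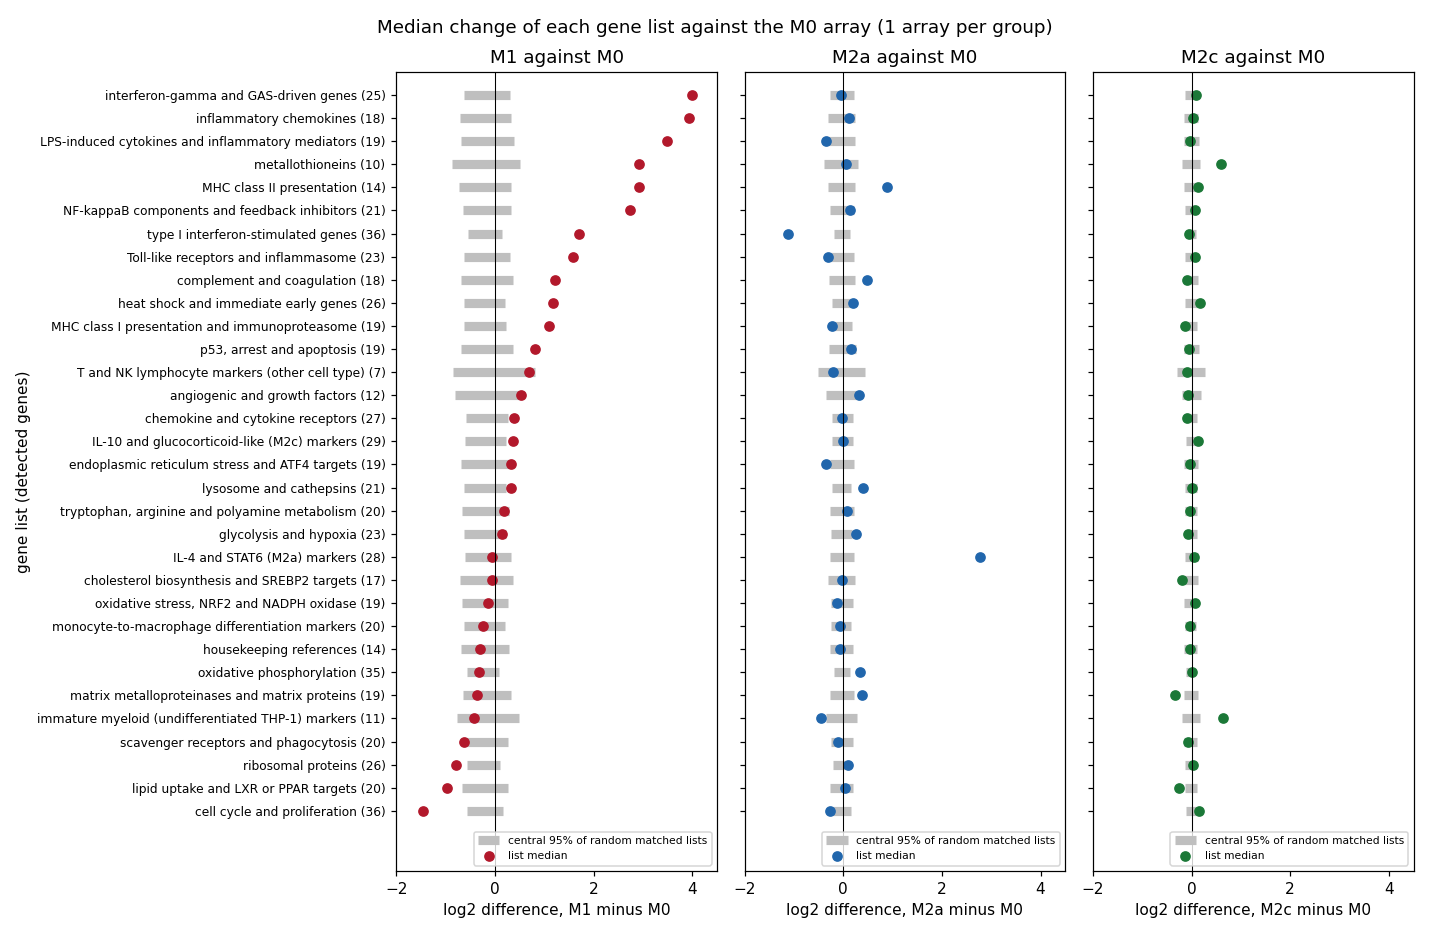
Median log2 difference of each of 32 gene lists (vertical axis, with the number of detected genes) on the M1, M2a and M2c arrays minus the M0 array (horizontal axes); each point is a list median from 1 array per group, and each grey bar spans the central 95% of 10000 random matched lists. Interferon-gamma genes stand at 3.99 on M1, IL-4 markers at 2.78 on M2a and type I interferon-stimulated genes at -1.12 on M2a, while the M2c medians lie between -0.34 and 0.63; the ribosomal protein median of M1, -0.79, shrinks to -0.14 with arrays scaled to a common median.

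The second comparison asked what IL-4 changed. The M2a array showed the known IL-4 response genes. TGM2, transglutaminase 2, rose 89.9-fold (6.49 on the log2 scale, against a mean of 2.44 for its other probes), ALDH1A2, which makes retinoic acid, was at least 142-fold higher, and the chemokines CCL26 and CCL18 were at least 53.1-fold and 26.0-fold higher. Over the alternatives for values the lowest log2 differences were 5.55 for TGM2, 5.48 for ALDH1A2, 4.22 for CCL26 and 3.34 for CCL18. Genes of the type I interferon response were lower. None of 19 MHC class I genes passed (median -0.23, percentile 3.99), and of 21 NF-kappaB genes CD80 and the dendritic cell marker CD83 rose while NFKBIZ fell (median 0.14, percentile 89.6), but 0 of them rose in the authors' table or with an offset of 50. Of 9860 genes tested 403 were higher and 497 lower, and 33 rose but 2 fell by at least 8-fold.

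Of 28 detected IL-4 and STAT6 markers 21 rose, 0 fell and 7 did not pass (median 2.78, percentile 100), or 2.56 with undetected sides at their bound. On M2a or M0 26 of them were detected, but on M2c or M0 only 16, so M0 detected at most 16. A marker undetected on M0 could rise but not fall, so the absence of falls was in part fixed by the detection rule. SPINT2, a serine protease inhibitor, rose by 4.93 and the C-type lectin CLEC4A by 4.34. The lectin receptor CD209 rose by 2.60 and the feedback inhibitor CISH was detected on the M2a array and on no other, while MRC1, ARG1, CCL17 and FN1, often used as M2 markers, and NOS2 and IL12B, often used as M1 markers, were not detected on any array; these 8 genes were looked up after the values were seen. Other large rises were of CKB (4.82), TSPAN7 (3.95), the surface glycoprotein CD52 (3.86), the neurturin receptor GFRA2 (3.33) and the succinate receptor SUCNR1 (3.28). The adhesion molecule VCAM1 was at least 36.7-fold higher (a mean log2 difference of 2.46 for its 2 other probes) and the water and glycerol channel AQP9 at least 15.2-fold. Of 14 MHC class II genes 6 rose and 0 fell (median 0.88, percentile 100), with HLA-DPA1 at least 7.98-fold higher, HLA-DMB up by 2.59 and HLA-DRB5 by 2.40. Lipid genes went both ways: LPL rose by 3.07 and FABP4 by 2.93, PDK4 was at least 2.35-fold lower and the cholesterol exporter ABCA1 fell 2.78-fold (3 of 20 higher, 2 lower, median 0.04, percentile 66.0).

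Type I interferon-stimulated genes made up the clearest fall. Of 36 detected members 23 fell and 0 rose (median -1.12, percentile 0.0), with IFI44L at -2.57, SAMD9 at -2.39, IFIT2 at -2.37 and TRIM22 at -2.23. Of them 16 fell in the authors' table, with arrays scaled to a common median 19, after normalization without the M1 array 23, and 20 did with an offset of 50. Of the 25 interferon-gamma genes, of which 18 were detected on M2a or M0, 2 fell and 2 rose (median -0.05, percentile 40.1, and 0.04 with arrays scaled to a common median): CXCL10, an interferon-inducible chemokine, fell by 2.74, while the feedback inhibitor SOCS1 was at least 6.26-fold higher and the adhesion molecule ICAM1 rose by 2.23. Of 23 Toll-like receptor and inflammasome genes 4 fell and 0 rose (median -0.31, percentile 1.38), but 1 fell in the authors' table (median -0.16), TLR7 being at least 3.13-fold lower, TLR8 at -1.37, CASP1 at -1.25 and MYD88 at -1.11.

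Inflammatory mediators split on the M2a array. Among 18 chemokines 6 rose, CCL8 by 3.21 and CCL2 by 1.77, and 3 fell, with CXCL8, the neutrophil chemokine, at -2.90 (median 0.11, percentile 83.7), but 4 rose and 1 fell in the authors' table. Among 19 LPS-type mediators, of which 12 were detected on M2a or M0, 3 fell and 2 rose (median -0.36, percentile 1.01), with 1 in each direction in the authors' table (median -0.27): IL1B was at -1.44 and PTGS2 at least 2.58-fold lower (-0.33 for its other probe), against a rise of 1.66 for the interleukin-1 receptor antagonist IL1RN. Further large falls were of the growth factor carrier IGFBP3 (-3.81), ANTXR1 (-2.84), the neuronal pentraxin NPTX1 (-2.59) and TDO2, a tryptophan dioxygenase (-2.52). PID1 was at least 5.69-fold lower, LGI2 at least 4.84-fold, ORM1 at least 3.85-fold, complement C3 at least 3.69-fold and CENPF at least 3.42-fold. Of 36 cell cycle genes TOP2A alone passed (-1.41; median -0.27, percentile 0.61).

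Of the changed genes with another detected probe, 206 of 216 (95.4%) moved the same way on the other probes, and 108 (50%) passed 2-fold there. The share of changed genes that were higher was 44.8% by the main method and 57.6% in the authors' table, where 170 were higher and 125 lower.

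The third comparison asked what IL-10 changed. The M2c array stayed closest to M0, and its largest single rise was that of C1QB, a chain of complement C1q. C1QB rose 16.3-fold (4.03 on the log2 scale, lowest over the alternatives for values 3.38) and the C1QA chain by 1.54. Between them in size lay MS4A3, a marker of myeloid precursors (2.60), CAV1, caveolin-1 (2.52, against 0.69 for its other probe), FCGBP (2.37), the selenium carrier SELENOP (2.11) and the protease inhibitor SLPI (1.96). Only 65 genes were higher and 43 lower of 9604 tested, and 1 rose but 0 fell by at least 8-fold.

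Of 29 detected IL-10 and glucocorticoid-like markers 6 rose and 0 fell (median 0.14, percentile 99.4): C1QB, SELENOP, C1QA, C1QC, FCGR2B and the scavenger receptor MARCO, which was at least 2.09-fold higher. On M1 the same list had a median of 0.37 (percentile 99.5), with 12 genes higher and 10 lower. C1QA, C1QB and C1QC, chains of the same C1q complex, were among the higher there, so their rises were not particular to M2c. C1QC and FCGR2B are outside the rule for named genes and were named after their values were seen. CD163, a haemoglobin scavenger receptor often used as an M2c marker, was 0.60 higher on the log2 scale and did not pass; it too was looked up afterwards. LAMP5 (1.68) and BMP8B (1.62) also rose, and the folate receptor FOLR2 was at least 4.81-fold, COL22A1 at least 3.10-fold, CCNA1 at least 2.55-fold and CEMIP at least 2.26-fold higher. Of 11 markers of immature myeloid cells MS4A3 and PRTN3, a granule protease (1.30), rose and 0 fell (median 0.63, percentile 100). MT1G (1.23) was the 1 of 10 metallothionein genes to rise, with a list median of 0.59 (percentile 100).

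The falls on the M2c array were small. They included the integrin chain ITGB7 (-1.80), the checkpoint receptor VSIR (-1.70), NPTX1 (-1.62), granulysin (GNLY, -1.58, against -0.63 for its other probe), PYROXD2 (-1.51), ORM1 (-1.40) and the proton pump subunit ATP6V0D2 (-1.40), and the receptor EPHB1 fell 2.82-fold. IGFBP5 was at least 3.36-fold lower, decorin (DCN) at least 2.72-fold, SPOCK1 at least 2.18-fold, the ectonucleotidase NT5E at least 2.03-fold and haptoglobin (HP) at least 2.00-fold. None of the 25 interferon-gamma genes, 36 type I interferon-stimulated genes, 19 MHC class I genes or 36 cell cycle genes passed in either direction. Their medians were 0.09 (percentile 92.8), -0.06 (19.6), -0.13 (4.56) and 0.16 (99.9), the last, that of cell cycle genes, above the range of random lists. On M2c or M0 only 17 of the 25 interferon-gamma genes and 17 of the 19 MHC class I genes were detected, so the others could not pass. The same limit held for LPS-type mediators (12 of 19 detected on M2c or M0) and chemokines (14 of 18). Among 19 LPS-type mediators EBI3 alone rose (1.47), and IL1B was 0.97 higher, under the threshold. Of 18 chemokines CXCL3, at least 1.79-fold higher, and CCL8 (1.41) rose, of 21 NF-kappaB genes CD80, at least 1.87-fold higher, and of 14 MHC class II genes HLA-DPA1, at least 1.61-fold higher. These changes rested on the correction of the background: the authors' table had 20 genes higher and 4 lower, so that 83.3% of the changed genes were higher against 60.2%, and 13 of the 26 genes with the largest changes stayed past 2-fold there. All 17 changed genes with another detected probe moved the same way on it, but only 6 (35.3%) passed 2-fold there.

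**Figure D2:**
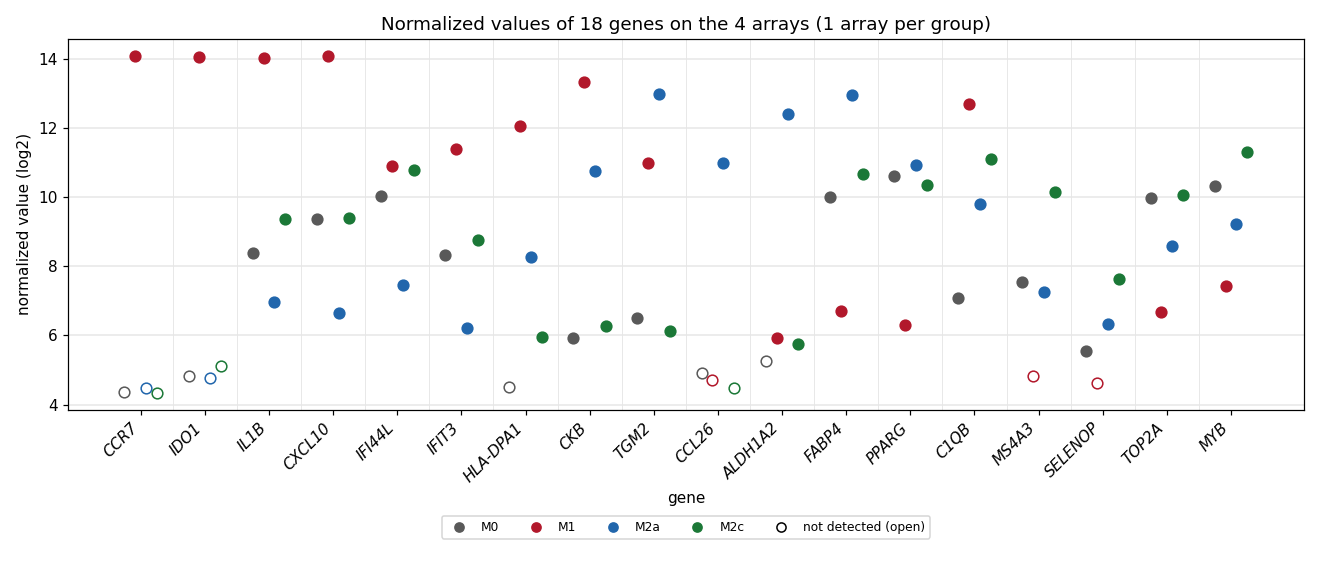
Normalized log2 values (vertical axis) of 18 genes (horizontal axis) on the M0, M1, M2a and M2c arrays, 1 point per array, open where the gene was not detected. CCR7 and IDO1 are detected on the M1 array and on no other, CCL26 on the M2a array and on no other, and C1QB lies above its M0 value by 5.61, 2.70 and 4.03 on the M1, M2a and M2c arrays.

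The polarised arrays were also compared with each other, which leaves the M0 array out; the genes named are the largest among those detected on both arrays. M1 against M2a gave 1542 genes higher and 1759 lower, M1 against M2c 1580 and 2075, and M2a against M2c 462 and 671. The share of changed genes that were higher was 46.7% for M1 against M2a and 43.2% for M1 against M2c, but 61.7% and 60.2% with arrays scaled to a common median, and 40.8% for M2a against M2c, but 51.0% in the authors' table. On M1, CXCL10 lay 7.47, IL1B 7.07, GBP5 6.57, CCL4L1 6.52 and ISG20 6.49 above M2a on the log2 scale, while ALDH1A2 lay at -6.48, FABP4 at -6.26, PPARG at -4.64, the adenosine receptor ADORA3 at -4.34 and CCL18 at -4.13. Against M2c, CKB (7.07), CCL3L1 (6.15), HLA-DPA1 (6.12), SERPING1 (6.01) and CCL3 (5.88) stood highest on M1 among genes detected on both arrays, and BMP8B (-5.06), CDCA7 (-4.19), GRAMD4 (-4.06), PPARG (-4.06) and FABP4 (-3.99) lowest. On M2a, TGM2 (6.88), ALDH1A2 (6.67), SPINT2 (5.23), CKB (4.48) and VCAM1 (4.14) lay above M2c, and IFI44L (-3.32), IGFBP3 (-3.22), GPR160 (-3.01), CXCL8 (-2.98) and MS4A3 (-2.91) below it. Of the 28 IL-4 markers 22 were higher on M2a than on M2c (median 2.87, percentile 100), and of the 36 type I interferon-stimulated genes 22 were lower (median -1.08, percentile 0.0). Immature myeloid markers were lower on M2a than on M2c for 7 of 11 genes (median -1.05, percentile 0.0).

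Some genes changed in the same direction on more than 1 polarised array. M1 and M2a shared 121 higher genes, VCAM1, CKB, AQP9, HLA-DPA1 and TGM2 the largest, against 39.2 for independent lists and at most 2 in simulations of unchanged arrays, which hold no real change. They shared 228 lower genes, led by ANTXR1 and CX3CR1, against 99.0 and at most 2. Another 70 genes were higher on M1 and lower on M2a, SERPING1, IL1B and ISG20 among them, against 61.5 for independent lists, and 63 were lower on M1 and higher on M2a, SUCNR1 and ITGAM among them, against 63.2. M1 and M2c shared 24 higher (6.08 for independent lists) and 13 lower genes (8.63), and M2a and M2c shared 22 higher (1.69) and 19 lower (2.25), each with at most 2 in simulations. Genes of these sets were named after their values were seen, by size where both arrays changed the same way and otherwise as examples. The log2 differences were correlated across 10395 genes, which are not independent replicates. The r was 0.22 for M1 and M2a, 0.05 for M1 and M2c and 0.15 for M2a and M2c. Simulations of unchanged arrays gave 0.50, a value fixed by the shared M0 array and equal noise on all arrays. Real changes alter r, so 0.50 is no yardstick for the measured values. The covariances were 0.167, 0.020 and 0.032, against 0.0411 simulated with a noise that is an upper estimate. They were 0.069, 0.006 and 0.009 in the authors' table and 0.102, 0.009 and 0.015 with an offset of 50, so their size depended on the processing. The M0 array cannot be split, so part of any overlap may come from that array.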

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

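Probes left unnamed here, which no comparison used, changed as well. On the M1 array 508 unnamed probes were at least 2-fold higher than on the M0 array, out of 3238 detected on either, and 436 were lower, the largest rise being 7.44 on the log2 scale. On the M2a array 99 unnamed probes were higher and 66 lower of 3206, with a largest rise of 7.40. On the M2c array 22 were higher and 11 lower of 2940, with a largest rise of 2.81. Named genes gave 1494 higher and 1902 lower of 9986 on M1, 403 and 497 of 9860 on M2a, and 65 and 43 of 9604 on M2c. Changes past 2-fold were thus seen among named genes too. The unnamed counts are of single probes and the named counts of genes, so they are not like units. On M1 and M2a rises outnumbered falls among unnamed probes, and falls outnumbered rises among named genes.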

How the results depend on the processing

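The check for reversals covered the genes with the largest changes, 26 per array against M0 and 10 per pair of polarised arrays. None of them reversed under the alternatives for values or the mean over probes. No list median against M0 outside the central range of random lists reversed either. Genes named only as list members and list medians of M2a minus M2c were not in this check. Sizes did move. Of the 26 genes with the largest changes against M0, the fold moved by over 1.5 times for 22 on M1, 20 on M2a and 19 on M2c in the authors' table and without background correction alike, and for 14, 13 and 6 with an offset of 50. Common-median scaling moved 10 on M1, and the mean over probes 7, 5 and 1. Detection at 0.05 and the mean over probes moved 0 of 128 list medians. Normalization without the M1 array, added after seeing the data, moved 0 of 96 and kept the counts within 1.5 times. The value table equals the authors' normalized table and was not run apart. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Counts below are higher, then lower.

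In the authors' table the counts were 847 and 796 for M1 against M0 (main 1494 and 1902), 170 and 125 for M2a (403 and 497), 20 and 4 for M2c (65 and 43), 886 and 736 for M1 against M2a (1542 and 1759), 905 and 913 for M1 against M2c (1580 and 2075), and 178 and 171 for M2a against M2c (462 and 671). Without background correction they were 844 and 789, 169 and 125, 20 and 4, 882 and 739, 902 and 912, and 178 and 172. Background left in shrinks every ratio, which by construction lowers such counts. With an offset of 50, which shrinks ratios in the same way, 1208 genes were lower on M1 than on M0, 230 and 237 changed on M2a, 29 and 13 on M2c, 1114 were lower on M1 than on M2a, 1368 lower on M1 than on M2c, and 256 and 309 changed between M2a and M2c. The 3-fold rule left 763 and 733, 135 and 77, 11 and 6, 798 and 685, 811 and 847, and 140 and 89, fewer by construction. Detection on both arrays left 1121 lower on M1 and 43 and 22 on M2c against M0, 1024 lower on M1 against M2a and 1239 against M2c, again by construction. Scaling to a common median left 1236 lower on M1 against M0 and 1373 against M2c, while the higher genes went up to 1960 and 2081. The median difference of the 10395 detected genes went from -0.17 to 0.12 against M0 and from -0.15 to 0.15 against M2c. M1 values were thus lifted as a whole, and why the scalings differ was not tested.

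Overlaps shrank likewise. In the authors' table and without background correction alike, M1 and M2a shared 44 higher and 36 lower genes (main 121 and 228), M1 and M2c 8 and 2 (24 and 13), M2a and M2c 5 and 2 (22 and 19), and all 3 arrays 2 and 2 (12 and 9). With an offset of 50 these were 61 and 88, 12 and 7, 9 and 7, and 4 and 4.

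List medians of M1 minus M0 in the authors' table and without background correction were 2.61 and 2.61 for LPS-type mediators (main 3.49), 3.27 and 3.28 for chemokines (3.93), 0.90 and 0.89 for Toll-like receptors (1.59), and 2.20 and 2.20 for metallothioneins (2.92). IL-4 markers of M2a minus M0 had 1.54 and 1.53, and 2.12 with an offset of 50 (2.78), and of M2a minus M2c 1.52, 1.5 and 2.11 (2.87). Scaling to a common median moved medians of M1 minus M0 to -0.14 for ribosomal proteins (-0.79), 0.03 for scavenger receptors (-0.63), 0.45 for matrix genes (-0.36), 0.55 for cholesterol synthesis (-0.06) and 0.40 for differentiation markers (-0.25). Each moved up, as did the median of the detected genes (-0.17 to 0.12). Why these lists moved further was not tested. Dim probes limit the precision: between arrays the log2 difference of undetected probes had an SD of 0.16 to 0.19.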

Other observations

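The test of interferon-stimulated genes between M2a and M2c below was chosen after values of several of the genes had been seen, and the other tests before their results were seen. Several other gene groups moved on these arrays. On M1, 10 of 18 complement and coagulation genes rose (median 1.21, percentile 100), with the protease C1S at least 15.9-fold higher and factor B (CFB) up by 3.58. Immediate early and heat shock genes rose for 14 of 26 and fell for 3 (median 1.17, percentile 100), led by the phosphatases DUSP5 (5.57) and DUSP1 (4.22), and 8 of 19 p53, arrest and apoptosis genes rose, GADD45B by 3.09 and CFLAR by 2.75, with 1 lower (median 0.82, percentile 99.99). Cytokine and chemokine receptors had 11 of 27 higher and 6 lower (median 0.39, percentile 99.4), with IL15RA at least 36.0-fold higher by the main normalization (1.83 on the log2 scale for its other probe). Of 29 IL-10 markers 12 rose and 10 fell on M1 (median 0.37, percentile 99.5), C1QB by 5.61 and HMOX1 by 3.18 against -2.84 for CD163, and of 28 IL-4 markers 7 rose, TGM2 by 4.48 (a mean of 2.24 for its 2 other probes), and 6 fell, F13A1 being at least 5.12-fold lower (median -0.05, and 0.42 with common-median scaling). Tryptophan, arginine and polyamine genes had 7 of 20 higher, WARS1 by 3.65, and 3 lower (median 0.19, percentile 94.8). Angiogenic and growth factors had 5 of 12 higher, VEGFC by 3.27, and 1 lower (0.53, percentile 97.3). Lysosome genes had 3 of 21 higher, LGMN by 2.78, and 1 lower (0.33, percentile 99.1), or 9 and 0 with common-median scaling. Stress genes of the endoplasmic reticulum had 6 of 19 higher, ATF3 by 2.83, and 2 lower, HSPA5 at -2.08 (0.33, percentile 98.1). Oxidative stress and NADPH oxidase genes had 6 of 19 higher, SOD2 by 3.26, and 4 lower (-0.14, and 0.40 with common-median scaling). Glycolysis genes had 2 of 23 higher, HK2 by 1.94 and PFKFB3 by 1.35 (0.14, percentile 94.5). Common-median scaling lifted the M1 values as a whole. Besides the IL-4 markers and oxidative stress genes above, further lists changed the sign of their M1 median under it. They were scavenger receptors (3 of 20 higher, 8 lower, -0.63 to 0.03), matrix genes (5 of 19 higher, 5 lower, -0.36 to 0.45) and cholesterol synthesis (3 of 17 higher, 1 lower, -0.06 to 0.55). The same held for oxidative phosphorylation (1 of 35 higher, 3 lower, -0.33 to 0.09) and housekeeping references (0 of 14 higher, 3 lower, -0.31 to 0.16). It also held for immature myeloid markers (0 of 11 higher, 4 lower, -0.42 to 0.03) and differentiation markers (3 of 20 higher, 7 lower, -0.25 to 0.40).

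On M2a, matrix genes (3 of 19 higher, 3 lower, median 0.38, percentile 99.9) included the elastase MMP12, at least 7.90-fold higher, and MMP7, at least 6.45-fold. Lysosome genes rose for 6 of 21 and fell for 1 (median 0.41, percentile 100), with the protease CTSB up by 1.61 and the lipase LIPA by 1.58. Glycolysis genes rose for 3 of 23 (0.26, percentile 99.7), HK3 by 2.57 and PFKP by 1.84, and 0 of 35 oxidative phosphorylation genes passed although their median was 0.34 (percentile 100). Complement genes had 4 of 18 higher and 3 lower (0.48, percentile 99.99), PLAU rising by 1.90, and scavenger receptors 4 of 20 higher and 2 lower (-0.10, and 0.09 with common-median scaling), ITGAM rising by 2.37 and AXL being at -1.77. The costimulator CD86 rose by 2.54 among differentiation markers (3 of 20 higher, 2 lower, -0.06, and 0.19 with common-median scaling). Immediate early and heat shock genes had 3 of 26 higher, DUSP5 by 1.83, and 1 lower, FOS at -2.20 (0.20, percentile 98.8), and growth factors 2 of 12 higher and 1 lower (0.32, percentile 98.0), TGFA being at least 3.56-fold higher. Stress genes of the endoplasmic reticulum had 1 of 19 higher, ATF3 by 1.63, and 1 lower, HSP90B1 at -1.14 (-0.35, percentile 0.66). Of 29 IL-10 markers C1QB (2.70), RNASE1 (2.69) and HMOX1 (1.74) rose and 3 fell (0.00, percentile 53.7), but 0 fell in the authors' table and 1 with an offset of 50. Immature myeloid markers had 3 of 11 lower (-0.45, percentile 0.56), LYZ at -2.07 and MYB at -1.11. The M2a medians of p53 genes (0.16, 2 of 19 higher and 1 lower), tryptophan and arginine genes (0.07, 1 of 20 higher and 3 lower, KYNU at -1.35), metallothioneins (0.05, 0 of 10) and ribosomal proteins (0.09, 0 of 26) lay inside the random range. So did the medians of further lists that changed sign with common-median scaling. They were cholesterol synthesis (-0.03 to 0.05, 0 of 17), oxidative stress genes (-0.12 to 0.13, 1 of 19 higher and 1 lower), housekeeping references (-0.07 to 0.04, 0 of 14) and receptors (-0.02 to 0.04, 1 of 27 higher and 2 lower).

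Several of these calls were lost in the authors' table. On M2a, complement genes had 2 higher and 1 lower there (median 0.25), scavenger receptors 1 and 1, p53 genes 0 and 0, and tryptophan and arginine genes 0 and 3. Matrix genes had 2 and 2, receptors 0 and 1, and differentiation markers 2 and 1. Growth factors had 2 and 0 (median 0.12), and oxidative stress genes 1 and 0. On M1, scavenger receptors had 1 and 4, matrix genes 4 and 2, growth factors 3 and 0, IL-4 markers 6 and 2, IL-10 markers 10 and 5, and housekeeping references 0 and 1. On M2c, IL-10 markers had 4 and 0 and complement genes 3 and 0, and 0 genes passed among MHC class II, NF-kappaB, Toll-like receptor, scavenger receptor, matrix, growth factor, heat shock, differentiation, receptor, IL-4 and T and NK cell lists.

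Markers of other cell types were mostly undetected: 7 of 22 T and NK cell genes, 3 of 12 B cell genes, 2 of 18 fibroblast and endothelial genes and 1 of 19 epithelial and lung cancer genes were detected on any array. The detected ones included IL7R (3.62) and MUC1 (3.79) higher on M1, CD79B higher on M1 (1.14) and M2a (1.08), GNLY and NKG7 lower on M2a (-1.82 and -1.48), and DCN at least 2.93-fold lower on M2a. The T and NK cell medians were 0.70, -0.20 and -0.10 on M1, M2a and M2c. On M2c, CD86 rose by 1.18, BCL2 by 1.45 and HSPA6 by 1.21, VEGFA was at least 1.89-fold lower, and 4 of 18 complement genes were higher, SERPINA1 by 1.32 after the C1q chains, with 2 lower (-0.09, percentile 12.2). Immediate early and heat shock genes had a median of 0.18 (percentile 99.9, 1 of 26 higher). Lists with medians outside the random range but few calls were matrix genes (-0.34, percentile 0.0, 2 of 19 lower), lipid genes (-0.26, percentile 0.02, 0 of 20), cholesterol synthesis (-0.20, percentile 0.65, 0 of 17), cell cycle genes (0.16, percentile 99.9, 0 of 36) and MHC class II genes (0.14, percentile 98.3, 1 of 14). Medians of the remaining lists on M2c lay inside the random range: IL-4 markers 0.05 (CD1A lower), scavenger receptors -0.07 (MSR1 up by 1.32), Toll-like receptors 0.07 (AIM2 up by 1.14), p53 genes -0.06 (BCL2), growth factors -0.07 (VEGFA), lysosome 0.01, glycolysis -0.08, oxidative phosphorylation 0.01, tryptophan and arginine -0.03, oxidative stress 0.06, endoplasmic reticulum stress -0.04, ribosomal proteins 0.03, housekeeping references -0.03, differentiation markers -0.04 (CD86) and receptors -0.09 (IL7R lower).

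Cell cycle and ribosomal protein genes were lower on the M1 array, with medians of -1.45 and -0.79. For cell cycle genes scaling of the arrays as the whole cause is argued against by a median of -1.31 with common-median scaling, and a trend with genomic length by a median of -1.34 after subtracting 50 genes matched on mean value and genomic length. Transcript length was not matched, so a loss of long transcripts stays open. For ribosomal protein genes the median shrank to -0.14 with common-median scaling, so scaling may account for the size of their fall against M0. That scaling also moved the median of the 10395 detected genes, from -0.17 to 0.12. The -0.14 was not set against matched genes, so it cannot show whether ribosomal protein genes stayed below equally bright genes. A general compression of bright probes is argued against by -0.57 after subtracting 50 genes matched on mean value, a gap to genes of like brightness. Slower division of M1 cells is a hypothesis for the cell cycle genes that stays open and that cell counts could decide; any difference of the single M1 culture or RNA stays open too.

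Type I interferon-stimulated genes were lower on the M2a array (median -1.12 against M0). A high reading of the M0 array for these genes is argued against by M2a minus M2c, which leaves M0 out, at -1.08, and scaling by -1.09 with common-median scaling. The cause stays open, since a difference of the single M2a culture cannot be told apart from the treatment.

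VCAM1, HLA-DPA1, C1QB, CCL8, CD80, COL22A1, EBI3, SLPI, FCAMR, HSD11B1, MSR1 and SERPINA1 were higher on all 3 polarised arrays than on M0, and 9 genes, PID1, NPTX1 and VSIR among them, were lower (0.46 expected of independent changes). The 12 higher genes exceeded the 0.18 expected of independent changes. That expectation ignores the M0 array shared by the 3 comparisons and takes every gene as equally likely to pass. The excess therefore cannot show whether the changes on the arrays were independent. In 100 simulations of unchanged arrays the highest count was 1, but these hold no real change, so noise of the shared M0 array that lifts real changes past 2-fold stays open. The rule mattered: C1QB and CCL8 alone, 2 genes, kept the pattern in the authors' table. A change common to the added cytokines is a hypothesis that further M0 cultures could decide, and a difference of the single M0 culture stays open.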
